A study of Homo sapiens with 9 samples.

How the data were processed

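RNA-seq libraries were made from total RNA with a SMARTer mRNA-seq kit, per the labels. The 9 libraries come from cells labelled HepG2, a human hepatocellular cell line, in 3 groups of 3: an untreated control, SKF-96365, which the series text calls an inhibitor of the cation channel TRPV2, and 2-APB, which it calls an agonist. Titles of the 2-APB samples read ABP, and their descriptions and value columns carry the name TRPV2. They were taken as 2-APB from the treatment label, and another meaning of that name cannot be excluded. The labels give no dose, exposure time, vehicle, batch or day, and do not say whether libraries of a group are separate cultures. P-values therefore measure only the spread between these samples. The numbers 1 to 3 carried by the libraries were treated as names, not as pairs.

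The deposited values are a normalized signal: per the labels, the authors divided gene counts by 1 DESeq2 size factor per library, with no version given. Aligner, counter, genome build, annotation and strand setting are not stated. The table held 61093 genes, of which 60605 had Ensembl identifiers and 488 were unnamed loci. Symbols were matched by identifier for 60463 genes (99.8%), with 130 symbols taken from GENCODE 29. Within each library, 100% of the values were whole multiples of its smallest value above 0, within 0.001 of a read. Whole reads were recovered from this in 8 libraries. For SKF-96365 3 the step was 0.992, and the check takes a step this near 1 as possible rounding. Its total was therefore treated as not certain, although its values were whole multiples too. Count models used the other 8 libraries, which left SKF-96365 1 and SKF-96365 2 in that group. Depth was 14786059 to 19026545 reads per library. PCR reads without molecular identifiers are not independent molecules, so intervals cover counting error only.

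The gene test was chosen before the data were examined. It was limma 3.58.1 with an intensity trend, in R 4.3.3, on log2 of the normalized count plus 1, over 17492 genes with a value of at least 10 in at least 3 of the 9 libraries. All 9 libraries shared 1 estimate of the spread per gene, with 3 two-sided contrasts and an F test over the groups. Calls needed a Benjamini-Hochberg adjusted p under 0.05. On simulated counts, limma recovered 48% of 100 genes shifted by 1 log2 unit and 95% of 100 genes shifted by 2, with 9 false calls. On 8 simulated libraries edgeR recovered 39% and 87% with 5 false calls, and DESeq2 55% and 96% with 41. The shifted genes were drawn from those with a mean of at least 50. Each gene was simulated independently, and no library stood with another group. These shares therefore do not give the power reached with the measured libraries.

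A total of 44 gene lists with 988 symbols were written before the data were examined, and 43 with at least 5 tested members were compared by limma's camera with a preset inter-gene correlation of 0.01. Adjustment ran over the 43 lists. Camera with an estimated correlation and fry, which tests whether members move on balance in 1 direction, were run beside it. Each list was also adjusted over the list alone.

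Genes were named by a rule set in advance: TRPV2, the called genes with the largest changes, called members of called lists, and the member with the highest mean of a list that was not called. As no gene was called, another rule was added after values were seen. For the 8 lists per contrast with the smallest camera p, it names the 3 members with a mean of at least 50 and the largest log2 fold change in camera's direction. The highest member is named for 8 lists that at least 1 comparison left uncalled.

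Alternatives were another pseudocount (0.5 or 5), no filter, a filter on a mean of at least 50, upper-quartile, quantile and total rescaling, no variance trend, a robust prior, only the 2 groups compared, the replicate number as a block, each library left out, and edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads. After the data were seen, fits were added without 2 libraries that stood with another group (control 3 and SKF-96365 1), and without these and 2-APB 3. A fit without the genes high in control 3 alone was added too. The correlation of the 2 responses across genes was set beside 100 simulated sets of unchanged groups that share the controls, with each gene drawn independently. Sets of the smaller group sizes were simulated later for the fits without libraries. All 280 partitions of the 9 libraries into 3 groups of 3 were enumerated for an exact test.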

Results

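RNA was sequenced from 9 libraries of cells labelled HepG2, a hepatocellular line, 3 each from control cells and cells given SKF-96365 or 2-APB. Totals were 16053348, 16846086 and 15999490 reads in control 1 to 3, 19026545, 16495997 and 17424625 in SKF-96365 1 to 3 (the last is not certain), and 14786059, 19008238 and 16714159 in 2-APB 1 to 3. Mitochondrially encoded genes took 6.90% to 8.04% of the signal. Of 61093 listed genes, 38944 had a value above 0 in some library and 17492 entered the tests.

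Transcripts that hepatocytes secrete in large amounts were near 0 in all 9 libraries. ALB, which encodes albumin, had a mean of 4.24 normalized counts with a highest library at 11.8. AFP, alpha-fetoprotein, had a mean of 4.07, and the lipoprotein gene APOA1 and the carrier gene TTR had means of 0.53 and 0.22. The 26 listed secretory genes together took 25.3 to 42.8 CPM, and 6 of them entered the tests. SERPINA1, the highest of these 6, stood at 369 ± 158 in control, 371 ± 55.2 with SKF-96365 and 275 ± 30.6 with 2-APB (SD, n = 3). Of 18 hepatocyte transcription factors, 6 had a mean of at least 50, among them GATA4 (333) and NR2F2 (2589), while HNF4A had a mean of 1.21. Of the 24 listed mesenchymal and matrix genes all entered the tests, and 21 had a mean of at least 50. Among genes picked after their values were seen, the intermediate filament gene VIM had a mean of 31329, the keratin gene KRT19 8345, the cadherin gene CDH2 1649 and the transcription factor gene ZEB1 1096.

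**Figure D1:**
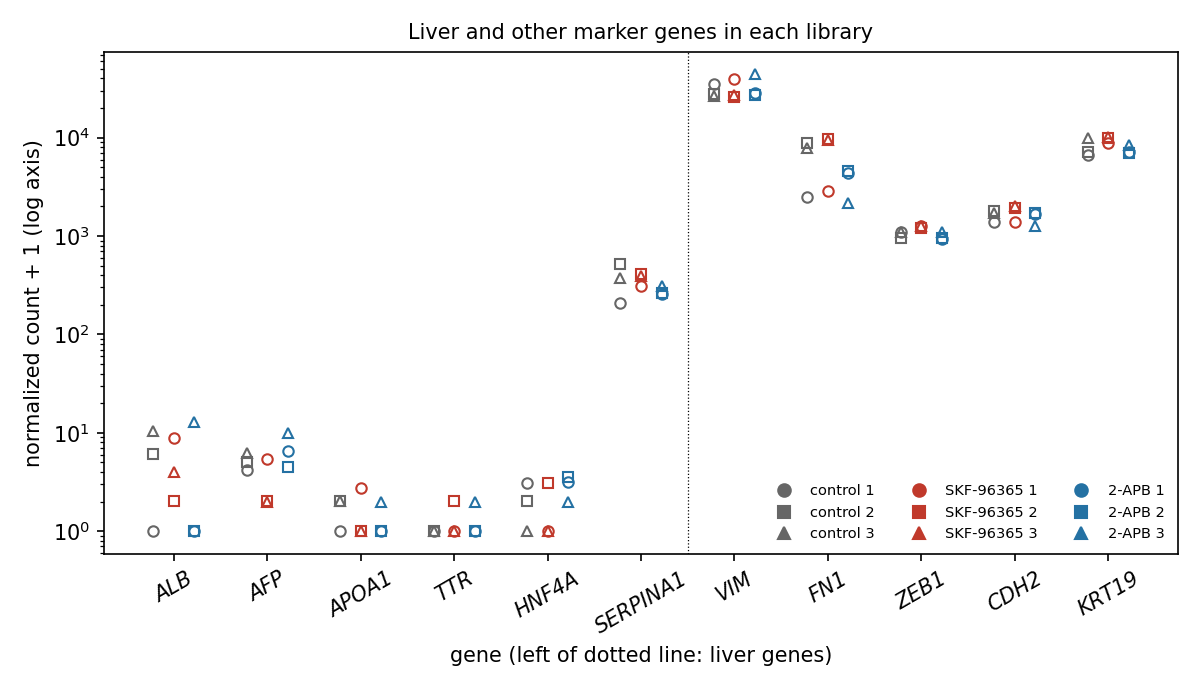
Normalized count plus 1 of 11 genes in each of the 9 libraries on a log axis, with colour for the group and symbol shape for the replicate. ALB, AFP, APOA1, TTR and HNF4A stay under 15 in every library, whereas the genes right of the dotted line have means from 1096 to 31329.

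Libraries did not fall into their 3 labelled groups. Over 17492 genes, control 3 had a mean Pearson r of 0.987 to SKF-96365 2 and 3 and 0.959 to control 1 and 2. SKF-96365 1 had a mean r of 0.978 to control 1 and 2 and 0.971 to SKF-96365 2 and 3. 2-APB 3 had a mean r of 0.980 both to control 1 and 2 and to 2-APB 1 and 2, and its closest library was SKF-96365 1 (0.988). Chi-square per degree of freedom on recovered reads, near 1 under counting error alone, was 2.14 for 2-APB 1 and 2. It was 3.66 for control 3 and SKF-96365 2. Other pairs within a labelled group ran from 18.1 (control 1 and 2) to 62.6 (control 2 and 3). Libraries of a group were thus unequally close, and whether close ones share a culture was not tested. Principal component 1 held 43.9% of the variance and had control 3, SKF-96365 2 and SKF-96365 3 at 48.4 to 48.8, and the other 6 libraries from -43.0 to -3.67. In an exact test over all 280 partitions into 3 groups of 3, 100 gave a pseudo-F at least as large as the labelled 1.12 (exact p = 0.357), and the highest was 3.51. Control 3 also held 98 genes at 20 or more and over 5 times the highest other library plus 1, against 0 to 2 such genes in the other libraries. They included the receptor tyrosine kinase genes ALK, at 1929 in control 3 and at most 14.2 elsewhere, RET, at 938 and at most 15.2, and ROS1, at 270 and at most 13.8. These 3 were picked after their values were seen.

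**Figure D2:**
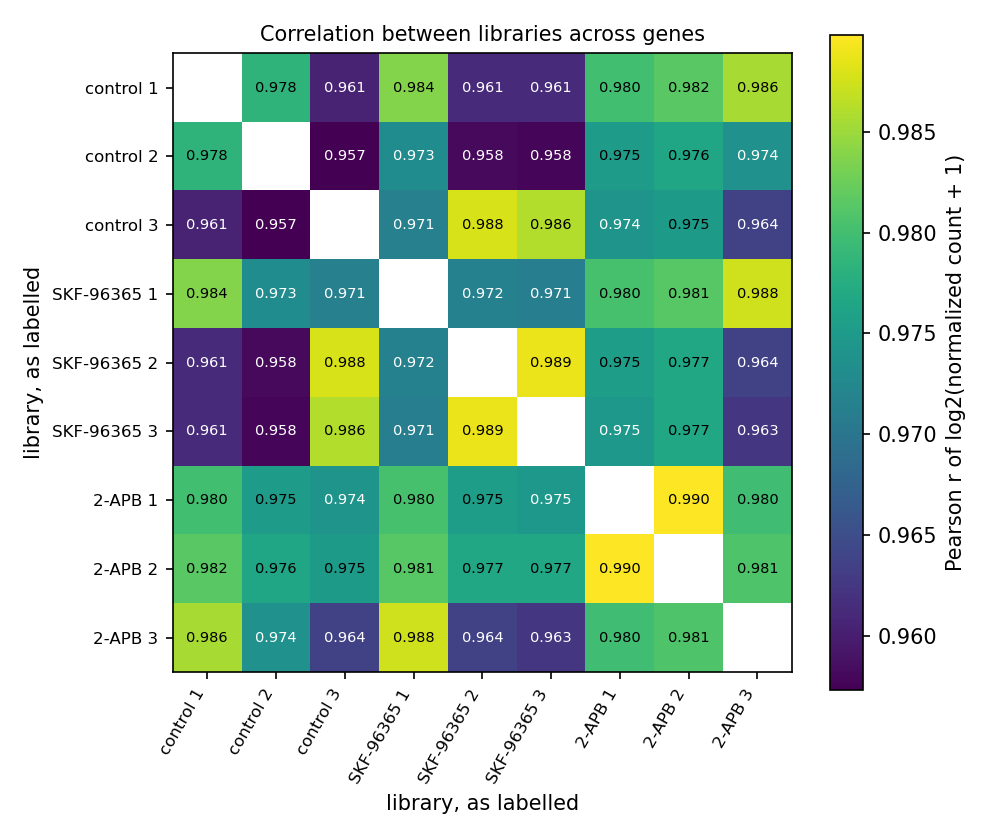
Pearson r between each pair of the 9 libraries on log2 of the normalized count plus 1 over 17492 genes. Control 3 is closer to SKF-96365 2 (0.988) and SKF-96365 3 (0.986) than to control 1 (0.961) and control 2 (0.957).

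SKF-96365 against control asks what the channel inhibitor does to transcript levels. With SKF-96365, in camera with the preset correlation, genes of DNA replication and the G1/S step lay lower as a group, and tubulin genes, mitosis genes and ribosome biogenesis genes lay lower too. Immediate early genes, NF-kB and inflammatory genes, replication-dependent histones and hypoxia genes lay higher. These 8 lists had the smallest p of the 13 called by camera, 8 of them higher and 5 lower, and 0 of the 13 were called with an estimated correlation. No single gene passed limma's test. The counts were 0 higher and 0 lower, with 699 of 17492 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.789. Leaving out 1 library moved the 699 to 248 (without control 2 or SKF-96365 3), 270 (SKF-96365 2), 389 (control 1), 444 (2-APB 2), 458 (2-APB 1), 2247 (SKF-96365 1) and 4460 (control 3). On 8 libraries edgeR called 0 genes (258 unadjusted) and DESeq2 called 2 (241 unadjusted). These fits lacked SKF-96365 3 and kept SKF-96365 1, which lay closer to control 1 and 2, so their few calls say little. The groups did not overlap in 6.20% of genes, where random splits average 10%. DESeq2's 2 calls, named after their values were seen, were the pseudogenes SPCS2P4 (log2 fold change -1.57, adjusted p = 0.0296) and SNRPGP10 (2.37, adjusted p = 0.0393). Reads of a pseudogene can be shared with its parent gene.

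All 34 tested DNA replication genes had negative log2 fold changes with SKF-96365 (mean -0.47, camera adjusted p = 2.61e-10; adjusted p = 0.782 with an estimated correlation). CDC6, which loads the replicative helicase, stood at 1645 ± 987 in control and 844 ± 439 with SKF-96365 (SD, n = 3). UHRF1, which maintains DNA methylation, stood at 2923 ± 1446 and 1578 ± 641, and the cyclin gene CCNE2 at 193 ± 151 and 94.5 ± 64.9. The list's score was -0.58 in control 3, -0.61 in SKF-96365 2 and -0.56 in SKF-96365 3, against 0.60 and 0.30 in control 1 and 2 and 0.09 in SKF-96365 1. The list's mean was -0.22 without control 1 and -0.81 without control 3, and in the same fits CCNE2 was -0.14 and -1.63, CDC6 -0.41 and -1.44, and UHRF1 -0.49 and -1.31. Of 14 tubulin and microtubule genes, 13 were negative (mean -0.55, adjusted p = 9.23e-05; adjusted p = 0.607 with an estimated correlation). The beta-tubulin gene TUBB4B had a log2 fold change of -0.96 (SE 0.56), and the alpha-tubulin genes TUBA1C and TUBA1B had -0.92 (SE 0.51) and -0.89 (SE 0.50). TUBA1B was at 3811 in control 3, 3595 in SKF-96365 2 and 3749 in SKF-96365 3, and from 9375 to 14648 in control 1, control 2 and SKF-96365 1. Without control 3 the mean of the tubulin list was -0.89 and TUBB4B, TUBA1C and TUBA1B were -1.65, -1.56 and -1.53, and without control 2 they were -0.62, -0.56 and -0.56. Mitosis and G2/M genes were negative in 32 of 34 (mean -0.22, adjusted p = 9.23e-05; adjusted p = 0.786 with an estimated correlation). Examples were the ubiquitin-conjugating enzyme gene UBE2C at -0.51 (SE 0.27), the transcription factor gene FOXM1 at -0.45 (SE 0.24) and the kinase gene CDK1 at -0.45 (SE 0.21). The call of the mitosis and G2/M list ended without control 2 (mean -0.066, adjusted p = 0.305) or SKF-96365 2 (-0.12, 0.0549), and its mean was -0.41 without control 3 and -0.38 without SKF-96365 1. UBE2C, FOXM1 and CDK1 were -0.77, -0.76 and -0.68 without control 3 and -0.34, -0.25 and -0.32 without control 2.

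Ribosome biogenesis and MYC target genes were negative in 24 of 28 (mean -0.19, adjusted p = 0.00293; adjusted p = 0.786 with an estimated correlation). The nucleolar protein genes NOP56 and NOP16 stood at -0.44 (SE 0.39) and -0.35 (SE 0.31), and the spermidine synthase gene SRM at -0.34 (SE 0.24). That call ended without control 1 (mean -0.033, adjusted p = 0.603), SKF-96365 2 (-0.084, 0.190) or SKF-96365 3 (-0.10, 0.0917), and the mean was -0.39 without control 3 and -0.38 without SKF-96365 1. NOP56 and SRM ran from -0.85 and -0.59 without control 3 to -0.13 and -0.19 without control 1, and NOP16 from -0.61 without SKF-96365 1 to -0.11 without control 1. The list's score was -0.34, -0.32 and -0.29 in control 3, SKF-96365 2 and SKF-96365 3, and 0.38, 0.17 and 0.26 in control 1, control 2 and SKF-96365 1.

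Among lists with higher levels, all 23 immediate early and calcium-responsive genes were positive (mean 0.50, adjusted p = 1.94e-06; adjusted p = 0.607 with an estimated correlation). The stress-induced transcription factor gene ATF3 stood at 197 ± 127 in control and 310 ± 46.3 with SKF-96365, the early response gene IER3 at 597 ± 307 and 966 ± 110, and the phosphatase gene DUSP5 at 858 ± 572 and 1331 ± 348 (SD, n = 3). ATF3 ran from 0.55 without control 1 to 1.31 without control 3, and IER3 and DUSP5 from 0.46 and 0.42 without control 2 to 1.20 and 1.30 without control 3. NF-kB and inflammatory genes were positive in 19 of 21 (mean 0.67, adjusted p = 8.23e-06; adjusted p = 0.607 with an estimated correlation). The cytokine genes IL1B, CXCL8 and IL1A had log2 fold changes of 2.12 (SE 0.96), 1.73 (SE 0.97) and 1.37 (SE 0.47). CXCL8 ranged from 113 to 998 in the control libraries and from 995 to 2828 with SKF-96365. Without control 2, IL1B was 0.71, CXCL8 0.78 and IL1A 0.77, and without control 3 they were 2.99, 2.34 and 1.94. Replication-dependent histones were positive in 13 of 15 (mean 0.83, adjusted p = 7.16e-06; adjusted p = 0.607 with an estimated correlation), with H2BC21 at 1.92 (SE 0.72), H2BC8 at 1.70 (SE 0.68) and H2BC4 at 1.53 (SE 0.51). The lowest values with 1 library left out were 1.28 and 1.01 for H2BC21 and H2BC8 without control 2, and 1.09 for H2BC4 without control 1. Without control 3 limma called all 3, at 2.99 (adjusted p = 0.0159), 2.73 (0.0109) and 2.30 (0.00391), and also ATF3 (1.31, 0.0403), IL1A (1.94, 0.0441) and SLC2A3 (1.79, 0.0403). Control 3 stood with SKF-96365 2 and 3, so leaving it out removes an overlap of the groups, and these p-values are optimistic. Replication-dependent histone messages mostly lack a poly(A) tail. Of 19 hypoxia genes, 14 were positive (mean 0.21, adjusted p = 0.00281; adjusted p = 0.607 with an estimated correlation), among them the glucose transporter gene SLC2A3 (1.11, SE 0.49), the stress gene NDRG1 (0.58, SE 0.22) and the collagen hydroxylase gene P4HA2 (0.45, SE 0.20). SLC2A3 was 0.73 without control 1, and P4HA2 was 0.28 without control 2 and 0.69 without control 3. The hypoxia call ended without control 1 (mean 0.14, adjusted p = 0.0687) or SKF-96365 1 (adjusted p = 0.0591). Without control 2 the means were 0.29 for the immediate early, 0.36 for the NF-kB and 0.48 for the histone list, and the histone mean was 1.33 without control 3. Scores of the histone list were 0.87 in control 3 and 0.41, 0.75 and 0.92 in SKF-96365 1 to 3, against -0.45 and -0.83 in control 1 and 2.

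The other 5 called lists were higher for mesenchymal and matrix genes (20 of 24 positive, adjusted p = 0.00612), the circadian clock (12 of 16, 0.0143), fatty acid oxidation (14 of 17, 0.0346) and the acute phase response (4 of 5, 0.0448), and lower for the heat shock response (16 of 19 negative, 0.0172). With an estimated correlation their adjusted p ran from 0.607 to 0.786. Each of these 5 calls also ended when single libraries were left out. The mesenchymal call ended without control 1 (mean 0.15, adjusted p = 0.113), control 2 (0.13, 0.0776), SKF-96365 2 (adjusted p = 0.0556) or SKF-96365 3 (0.0628), and its mean was 0.50 without control 3 and 0.42 without SKF-96365 1. The circadian call ended without control 1 (adjusted p = 0.0896), control 2 (mean 0.20, adjusted p = 0.0698) or SKF-96365 3 (0.0668), and its mean was 0.64 without control 3. The fatty acid oxidation call ended without control 1 (adjusted p = 0.240) or any SKF-96365 library (0.0591, 0.0539 and 0.0628), with no filter (0.0988) and with no variance trend (0.0560), and its mean was 0.44 without control 3. The acute phase call ended without control 1 (0.0906), control 2 (mean 0.26, adjusted p = 0.182), SKF-96365 1 (0.129) or SKF-96365 2 (0.0549), and with no filter (0.265), upper-quartile rescaling (0.0502), quantile normalization (0.0505) or no variance trend (0.0560). The heat shock call ended without control 1 (mean -0.11, adjusted p = 0.447), SKF-96365 2 (-0.15, 0.190) or SKF-96365 3 (0.0917) and with a mean of at least 50 (0.0598), and its mean was -0.43 without control 3 and -0.40 without SKF-96365 1.

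Adjusted over the list alone, 1 gene passed over the 43 lists, a hepatocyte transcription factor. Without control 3 limma called 111 genes higher and 62 lower with SKF-96365, and without both control 3 and SKF-96365 1 it called 2295 and 2528. These 2 libraries were picked because they stood with the other group, which makes the p-values of that fit optimistic. Leaving out control 3 alone removes an overlap of the groups in the same way. Without any other single library, 0 genes were called. The number of called lists was 7 without control 1, 8 without SKF-96365 2 and 17 without control 3.

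**Figure D3:**
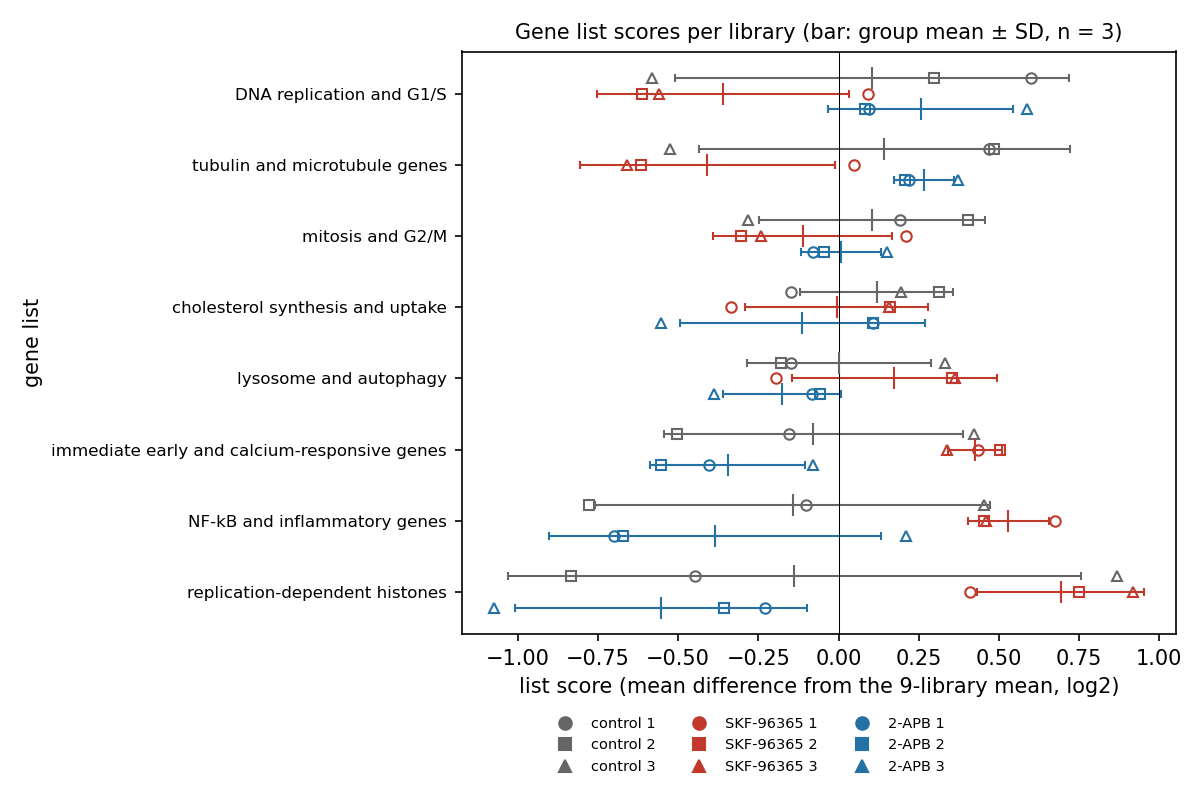
Scores of 8 gene lists per library, the mean over members of log2 of the normalized count plus 1 minus each gene's mean over 9 libraries, with bars for the group mean ± SD (n = 3). For DNA replication, control 3 (-0.58) lies beside SKF-96365 2 (-0.61) and SKF-96365 3 (-0.56), and SKF-96365 1 (0.09) beside 2-APB 1 (0.10).

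2-APB against control asks what the channel agonist does. With 2-APB, lysosome and autophagy genes, cholesterol genes, metallothioneins, p53 targets, immediate early genes and NF-kB genes lay lower as groups in camera with the preset correlation, and no list was called higher. Of these 6 called lists, 0 were called with an estimated correlation and 0 by fry. Of 10 splits of the 6 libraries, the labelled one included, 9 called at least 6 lists. The number of calls therefore does not show an effect of 2-APB. No gene passed limma's test. The counts were 0 higher and 0 lower, with 489 genes (2.80%) at an unadjusted p under 0.05, and the smallest adjusted p was 0.9995. The 489 became 241 without 2-APB 1, 291 without 2-APB 2, 734 without control 1 and 1662 without control 3. On 8 libraries edgeR called 0 genes (367 unadjusted) and DESeq2 0 (350 unadjusted). The groups did not overlap in 7.57% of genes, where random splits average 10%.

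Lysosome and autophagy genes were negative in 27 of 29 (mean -0.18, adjusted p = 0.000787; adjusted p = 0.985 with an estimated correlation). NPC1, which exports cholesterol from lysosomes, stood at 8735 ± 3959 in control and 4183 ± 259 with 2-APB, the protease gene CTSL at 3878 ± 1094 and 2455 ± 181, and FNIP1 at 1403 ± 375 and 1113 ± 141 (SD, n = 3). Cholesterol synthesis and uptake genes were negative in 22 of 25 (mean -0.23, adjusted p = 0.000787; adjusted p = 0.985 with an estimated correlation). INSIG1, which retains the sterol-regulated SREBP complex in the endoplasmic reticulum, stood at -0.72 (SE 0.59), and the synthesis enzyme genes HMGCS1 and MSMO1 at -0.64 (SE 0.41) and -0.62 (SE 0.34). The cholesterol score was -0.55 in 2-APB 3 and 0.11 in both 2-APB 1 and 2-APB 2, and the call ended without 2-APB 3 (mean -0.012, adjusted p = 0.759) or control 2 (-0.14, 0.139), with a mean of -0.37 without control 1. INSIG1 ran from -1.17 without control 1 to -0.21 without 2-APB 3, and HMGCS1 and MSMO1 from -0.98 and -0.86 to -0.26 and -0.32 in the same fits. Metallothioneins and zinc transport genes were negative in 7 of 7 (mean -0.36, adjusted p = 0.00406; adjusted p = 0.415 with an estimated correlation, and 0.0997 by fry). The zinc exporter gene SLC30A1 stood at 980 ± 204 and 709 ± 188, MT2A at 6910 ± 890 and 5795 ± 1513, and MT1E at 1425 ± 132 and 1202 ± 71.9. The lysosome call ended without control 3 (mean -0.013, adjusted p = 0.595) or 2-APB 3 (-0.073, 0.252), with a mean of -0.27 without control 2, and the metallothionein call without control 3 (0.0637). FNIP1 ran from -0.43 without control 1 to -0.10 without control 3, SLC30A1 from -0.63 without 2-APB 2 to -0.24 without 2-APB 3, and MT2A from -0.48 without 2-APB 3 to -0.11 without 2-APB 1.

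Among p53 targets and apoptosis genes 21 of 24 were negative with 2-APB (mean -0.17, adjusted p = 0.0149; adjusted p = 0.985 with an estimated correlation). The stress cytokine gene GDF15 was at 404, 298 and 4830 in control 1 to 3 and from 389 to 558 with 2-APB. GADD45A and PHLDA3, both induced by p53, had log2 fold changes of -0.48 (SE 0.41) and -0.44 (SE 0.14). Immediate early genes were negative in 17 of 23 (mean -0.27, adjusted p = 0.0161; adjusted p = 0.985 with an estimated correlation), with the kinase gene SIK1 at 46.3, 50.7 and 729 in control 1 to 3, and the phosphatase genes DUSP5 at 858 ± 572 in control and 461 ± 128 with 2-APB and DUSP1 at 1802 ± 932 in control and 1125 ± 96.9 with 2-APB (SD, n = 3). NF-kB genes were negative in 17 of 21 (mean -0.24, adjusted p = 0.0331; adjusted p = 0.989 with an estimated correlation), with the chemokine genes CXCL2 and CXCL3 at -0.96 (SE 0.61) and -0.72 (SE 0.73) and the interleukin gene IL6 at -0.56 (SE 0.21). Without control 3 the p53 call ended (mean -0.038, adjusted p = 0.570), and the camera direction of the immediate early and NF-kB lists turned (mean log2 fold change -0.018 and 0.053). GDF15, GADD45A and SIK1 then stood at 0.49, 0.012 and 0.22, and DUSP5 and DUSP1 at -0.22 and -0.17. Without control 2, GDF15, GADD45A, DUSP5 and DUSP1 stood at -1.51, -0.92, -1.11 and -0.86, and SIK1 was -1.76 without control 1. The calls of both lists also ended without 2-APB 1 (adjusted p = 0.0815 and 0.314) or 2-APB 2 (0.311 and 0.329), and the NF-kB call with a mean of at least 50 (0.0765) or no variance trend (0.0614). Their means were -0.48 and -0.56 without control 2 and -0.16 and -0.10 without 2-APB 2, and the NF-kB mean was -0.088 without 2-APB 1 and -0.54 without 2-APB 3. CXCL2 and CXCL3 were -1.64 and -1.53 without control 2 and -0.46 and -0.14 without control 3. Adjusted over the list alone, 1 gene passed, a hepatocyte secretory gene. The number of called lists was 13 without control 1 and 10 without control 2. Without control 3, SKF-96365 1 and 2-APB 3, picked for where they stood, limma called 722 genes higher and 1013 lower with 2-APB, and the mean of the lysosome list was 0.09. In that fit none of the 6 lists above kept its call (adjusted p from 0.0805 to 0.921). The 10 lists it called with the preset correlation were others, with DNA replication at a mean of -0.36 (0.15 with all libraries) and histones at 0.35 (-0.42), and 0 were called with an estimated correlation (smallest adjusted p = 0.494).

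2-APB against SKF-96365 sets the 2 compounds side by side. DNA replication and tubulin genes lay higher with 2-APB, and immediate early, NF-kB, histone, lysosome, p53 and mesenchymal genes lay lower, in camera with the preset correlation. Of the 43 lists camera called 13, of which 4 were higher and 9 lower, and 0 with an estimated correlation (smallest adjusted p = 0.513). Of 10 splits of these 6 libraries, the labelled one included, 4 called at least 13 lists. The number of calls therefore does not show a difference between the compounds. No gene passed limma's test. The counts were 0 higher and 0 lower, with 1277 genes (7.30%) at an unadjusted p under 0.05 and a smallest adjusted p of 0.684. The 1277 became 478 and 524 without SKF-96365 3 and 2, 610 and 689 without 2-APB 1 and 2, 2217 without control 3 and 2980 without SKF-96365 1. On 8 libraries edgeR called 0 genes (492 unadjusted) and DESeq2 1, the pseudogene SNRPGP10 (log2 fold change -2.44, adjusted p = 0.0385; 483 unadjusted). The groups did not overlap in 17.0% of genes, where random splits average 10%. As genes move together, a single split can lie far from that average, so the 17.0% does not show a difference.

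All 34 DNA replication genes were positive (mean 0.62, adjusted p = 6.25e-14; adjusted p = 0.595 with an estimated correlation). CCNE2 stood at 94.5 ± 64.9 with SKF-96365 and 256 ± 104 with 2-APB, CDC6 at 844 ± 439 and 1641 ± 509, and the transcription factor gene E2F2 at 198 ± 82.9 and 396 ± 97.1 (SD, n = 3). Tubulin genes were positive in 12 of 14 (mean 0.68, adjusted p = 8.21e-06; adjusted p = 0.580 with an estimated correlation), with TUBB4B at 1.34 (SE 0.56), TUBA1B at 1.21 (SE 0.50) and TUBA1C at 1.16 (SE 0.51). Immediate early genes were negative in 23 of 23 (mean -0.77, adjusted p = 4.11e-11; adjusted p = 0.513 with an estimated correlation). SIK1, DUSP5 and ATF3 had log2 fold changes of -1.53 (SE 1.00), -1.52 (SE 0.40) and -1.08 (SE 0.35). NF-kB genes were negative in 19 of 21 (mean -0.92, adjusted p = 1.96e-09; adjusted p = 0.513 with an estimated correlation), and 6 passed when adjusted over the list alone. CXCL8 stood at 1612 ± 1053 with SKF-96365 and 547 ± 705 with 2-APB, with 2-APB 3 at 1361. CXCL2 was at -2.02 (SE 0.61) and IL1B at -1.63 (SE 0.96). SIK1 ran from -2.37 without SKF-96365 1 to -0.85 without SKF-96365 2.

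Histones were negative in 14 of 15 with 2-APB (mean -1.25, adjusted p = 9.27e-09; adjusted p = 0.513 with an estimated correlation), and 6 passed when adjusted over the list alone. H2BC21 stood at 658 ± 190 with SKF-96365 and 93.7 ± 27.9 with 2-APB, H2BC8 at 608 ± 116 and 130 ± 30.3, and H2BC7 at 105 ± 46.9 and 10.2 ± 4.17 (SD, n = 3). With only these 2 groups in the fit limma called H2BC21 (adjusted p = 0.0431) and H2BC8 (0.0331) lower, and without control 3 it called both as well (0.0140 and 0.0190). Lysosome genes were negative in 25 of 29 (mean -0.35, adjusted p = 1.14e-06; adjusted p = 0.595 with an estimated correlation), with NPC1 at -1.21 (SE 0.39), the melanosome and lysosome gene GPNMB at -0.93 (SE 0.67) and CTSL at -0.92 (SE 0.21). The lysosome mean was -0.53 without SKF-96365 1, and GPNMB ran from -1.54 without SKF-96365 1 to -0.42 without 2-APB 3. Of 24 p53 targets 19 were negative (mean -0.38, adjusted p = 4.2e-05; adjusted p = 0.513 with an estimated correlation). GDF15 stood at 3349 ± 1914 and 495 ± 91.7, GADD45A at 4193 ± 1358 and 1789 ± 383, and the cell cycle inhibitor gene CDKN1A at 7319 ± 939 and 4128 ± 556. Mesenchymal and matrix genes were negative in 20 of 24 (mean -0.33, adjusted p = 0.000133; adjusted p = 0.595 with an estimated correlation), with the transcription factor gene SNAI2 at -0.99 (SE 0.61), fibronectin gene FN1 at -0.87 (SE 0.56) and the collagen crosslinker gene LOX at -0.83 (SE 0.43). FN1 ran from -1.45 without SKF-96365 1 to -0.52 without 2-APB 3. In SKF-96365 1, GDF15 was at 1138, NPC1 at 5333 and FN1 at 2869, against 4444 to 4463, 12783 to 13290 and 9529 to 9687 in the other SKF-96365 libraries.

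The circadian clock (14 of 16 negative, adjusted p = 0.00253), interferon-stimulated genes (18 of 22, 0.0145) and the acute phase response (4 of 5, 0.0207) were lower, and nuclear genes of oxidative phosphorylation (37 of 40 positive, 0.0145) and ribosome biogenesis genes (24 of 28, 0.0398) were higher. Their adjusted p with an estimated correlation ran from 0.513 to 0.794. The oxidative phosphorylation call ended without SKF-96365 2 (mean 0.027, adjusted p = 0.430), SKF-96365 3 (0.055, 0.105) or 2-APB 3 (0.055, 0.183), and its mean was 0.18 without SKF-96365 1. The ribosome biogenesis call ended without SKF-96365 2 (mean 0.056, adjusted p = 0.561), SKF-96365 3 (0.075, 0.360), 2-APB 3 (0.013, 0.980) or control 2 (adjusted p = 0.0530), with a mean of at least 50 (0.0592) and with no variance trend (0.0938), and its mean was 0.35 without SKF-96365 1. The interferon call ended without SKF-96365 3 (adjusted p = 0.0673), and the acute phase call without SKF-96365 1 (0.0868) and with no filter (0.393). Over all lists 16 genes passed when adjusted over the list alone. With only these 2 groups in the fit 4 genes were called lower, and without control 3 also 4. Without SKF-96365 1, camera called 21 lists. Without control 3 and SKF-96365 1, limma called 1126 genes higher and 1157 lower.

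**Figure D4:**
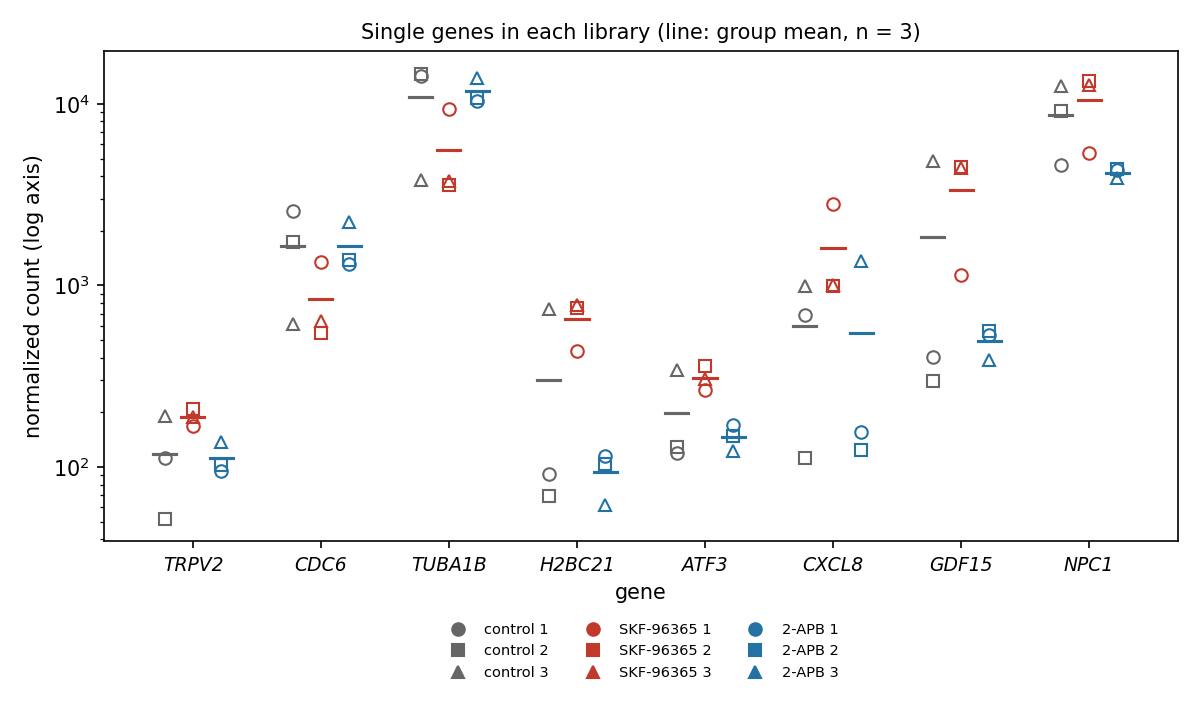
Normalized counts of 8 genes in each library on a log axis, with a line at the group mean (n = 3). H2BC21 lies at 744 in control 3, against 91.5 and 69.0 in control 1 and 2 and 62.1 to 115 with 2-APB.

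TRPV2, on chromosome 17 from 16415542 to 16437003 on the plus strand in GENCODE 29, was the channel named by the series. It was at 112, 51.7 and 191 normalized counts in control 1 to 3, with 118 ± 69.9 in control, 189 ± 20.04 with SKF-96365 and 112 ± 22.4 with 2-APB (SD, n = 3). Its limma log2 fold change was 0.85 (SE 0.38, adjusted p = 0.789) with SKF-96365, 0.09 (adjusted p = 1.00) with 2-APB, and -0.77 (adjusted p = 0.694) for 2-APB against SKF-96365. The 2-APB value was -0.0021 with quantile normalization, -0.40 without control 2, -0.067 without 2-APB 3, -0.083 in edgeR and 0.53 without control 3. The SKF-96365 value was 0.36 without control 2, 1.29 (adjusted p = 0.0593) without control 3 and 1.37 (adjusted p = 0.0153) without control 3 and SKF-96365 1, which were left out for where they stood, and its adjusted p over 24 alternatives ran from 0.00932 to 1.00. Among the 24 listed TRP channel genes 11 entered the tests, and with all libraries the list was called in none of the 3 contrasts (camera adjusted p = 0.122, 0.973 and 0.0939). Without control 3, SKF-96365 1 and 2-APB 3, picked for where they stood, camera with the preset correlation called it in each (adjusted p = 0.00324, 0.0142 and 0.0115). With an estimated correlation it was called in none (0.307, 0.494 and 0.276). The list's mean with 2-APB against control was then 0.27, and -0.055 with all libraries. TRPM7, the highest of the list, stood at 2563 ± 365 in control, 3049 ± 424 with SKF-96365 and 2533 ± 279 with 2-APB.

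Several calcium and stress lists were not called, which does not show equal levels. The list of calcium entry, stores and pumps was not called (camera adjusted p = 0.713, 0.266 and 0.574 in the 3 contrasts). Its highest member CALR, a calcium-binding chaperone gene, stood at 16031 ± 618 in control, 16802 ± 584 with SKF-96365 and 16942 ± 237 with 2-APB (SD, n = 3). HSPA5, the main chaperone of the endoplasmic reticulum, stood at 24515 ± 2764, 25217 ± 5370 and 25544 ± 4452 in the same order. The amino acid transporter gene SLC7A5, of the ATF4 list, stood at 13096 ± 1438, 11342 ± 719 and 12820 ± 839. TXNRD1, of the NRF2 list, was at 49475 ± 3708, 50545 ± 4338 and 49538 ± 736. The glycolytic enzyme gene ENO1 was at 51706 ± 4211, 49793 ± 2387 and 53155 ± 1432, and IFITM3, of the interferon list that was called between the compounds only, at 7426 ± 451, 7623 ± 300.2 and 7513 ± 534. The endoplasmic reticulum, ATF4, NRF2 and glycolysis lists were called in none of the 3 contrasts.

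Both responses share the same 3 controls. Across 17492 genes, which are not independent replicates, the log2 fold changes of SKF-96365 and 2-APB had a Pearson r of 0.353. Unchanged groups simulated against the same controls, with each gene drawn independently, gave a mean of 0.4998 (0.473 to 0.528). The measured genes moved together, with an estimated correlation of 0.92 within the DNA replication list. The simulated ranges are therefore too narrow, and a value outside them does not show a departure from unchanged groups. The signs were the same in 59.6% of genes, against 66.7% in the simulations. Leaving out control 1, 2 or 3 gave an r of 0.455, 0.261 or 0.708, where unchanged groups of those sizes gave 0.5998 (0.575 to 0.623), and leaving out SKF-96365 1 gave 0.2199, against 0.445 (0.414 to 0.486). The F test over the 3 groups called 0 genes with limma (smallest adjusted p = 0.862), 0 with edgeR and 2 with DESeq2, and limma called 5 without control 3 and 3547 without control 3 and SKF-96365 1.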

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

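The fits without 2 libraries (control 3, SKF-96365 1) or 3 libraries (also 2-APB 3) and without the genes high in control 3 alone were chosen after the results were seen. Over 128 results and 3019 alternative values, 2747 were counted as the same, 67 became weaker, 99 stronger, 58 reversed and 48 moved. For lists and genes, the same meant an equal direction and side of the threshold. For counts and the correlation it meant a change within a set limit. As no gene was called in the main fit, a gene could not become weaker. Of the called lists, 7 became weaker without control 1, and 8 without SKF-96365 2 or without SKF-96365 3. The median SE of a log2 fold change was 0.228. In self-tests DESeq2 gave 41 false calls, more than limma (9) or edgeR (5). With the replicate block, genes called stayed at 0 and lists were 15, 8 and 13 in the order SKF-96365 against control, 2-APB against control, 2-APB against SKF-96365.

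With an estimated correlation 0, 0 and 0 lists were called, and by fry 0, 0 and 0. Quantile normalization gave 12 lists for 2-APB against control. A fit of only the 2 groups gave 4 genes lower with 2-APB than SKF-96365. DESeq2 on 8 libraries called 1 gene higher and 1 lower with SKF-96365, 1 lower with 2-APB than SKF-96365, and 2 over the 3 groups. The correlation of the responses was 0.4638 with no filter, 0.2694 with a mean of at least 50 and 0.2946 with quantile normalization. The cause was not tested.

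Leaving out 1 library at a time, genes higher with SKF-96365 ranged from 0 to 111 and lower from 0 to 62, genes lower with 2-APB than SKF-96365 from 0 to 4, and genes differing over the groups from 0 to 5, each highest value without control 3. Lists ranged from 7 (without control 1) to 17 (without control 3) for SKF-96365, 6 to 13 (without control 1) for 2-APB, and 10 to 21 (without SKF-96365 1) between the compounds. The correlation ranged from 0.2199 without SKF-96365 1 to 0.7077 without control 3.

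Without 3 libraries, genes called were 3107 higher and 3462 lower with SKF-96365, 722 and 1013 with 2-APB, 1232 and 1343 between the compounds, and 5857 over the groups. Lists were 19, 10 and 20 with the preset correlation and 0, 0 and 0 with an estimated correlation (smallest adjusted p = 0.2145, 0.494 and 0.1343), and the correlation of the responses was 0.6793, where unchanged groups of those sizes gave 0.5003. Without 2 libraries, genes called were 2295 and 2528 with SKF-96365, 1126 and 1157 between the compounds, and 3547 over the groups. There were 21 lists between the compounds and a correlation of 0.649, against 0.5461 for unchanged groups. The simulated groups drew each gene independently, so they do not decide what these correlations mean. Control 3 and SKF-96365 1 were left out because they stood with another group. 2-APB 3 had a mean r of 0.980 both to 2-APB 1 and 2 and to control 1 and 2. As all were picked for where they stood, the p-values of both fits are too small.

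Signs that turned, all as log2 fold changes and with the cause not tested, were as follows. Against control with 2-APB, upper-quartile rescaling gave TRPM7 0.0266 and SLC7A5 0.0128, total rescaling 0.0346 and 0.0208, and quantile normalization 0.0451 and 0.0328, with TRPV2 at -0.0021. Quantile normalization gave TXNRD1 -0.0108 with SKF-96365. In edgeR, SERPINA1 was -0.0277 with SKF-96365 and TRPV2 -0.0833 with 2-APB.

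Without 3 libraries and with SKF-96365, HSPA5 was -0.2371 and TXNRD1 -0.0849. With 2-APB the lysosome list was 0.093, FNIP1 0.0067, INSIG1 0.1974, GDF15 0.6545, SIK1 0.2599, TRPM7 0.1923, HSPA5 -0.1823, TXNRD1 -0.0636 and ENO1 -0.0278. Without 2 libraries and with SKF-96365, HSPA5 was -0.2371 and TXNRD1 -0.0849. With 2-APB the immediate early list was -0.0176 (camera's direction turned, the mean did not), the NF-kB list 0.0534, GDF15 0.4916, GADD45A 0.0123, SIK1 0.2177, TRPM7 0.101, HSPA5 -0.0433, TXNRD1 -0.0537 and ENO1 -0.0068.

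Leave-one-out ranges of results that reversed were, with 2-APB, immediate early list -0.4793 to -0.0176, NF-kB list -0.5612 to 0.0534, GDF15 -1.5149 to 0.4916, GADD45A -0.9246 to 0.0123, SIK1 -1.7567 to 0.2177, TRPV2 -0.4032 to 0.5289, TRPM7 -0.0793 to 0.101, HSPA5 -0.0872 to 0.1289, SLC7A5 -0.0723 to 0.0616, TXNRD1 -0.0537 to 0.0545, ENO1 -0.0068 to 0.1065 and IFITM3 -0.0347 to 0.0767. With SKF-96365 they were HSPA5 -0.1419 to 0.1222, TXNRD1 -0.0282 to 0.0972, ENO1 -0.1018 to 0.0115, SERPINA1 -0.2714 to 0.3946 and IFITM3 -0.012 to 0.072.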

Other observations

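The tests of exchanged labels, of hepatocyte transcripts, of the cancer gene panel and of gene calls in splits were chosen after the results were seen. The tests of depth, other origin, genomic DNA, other cell types, list splits and drawn partitions had been set before.

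Genes among the 15 largest loadings at either end of principal component 1, picked after their values were seen, followed the set of control 3, SKF-96365 2 and SKF-96365 3. GJA1, the gap junction gene, was at 179, 194 and 187 in these 3 libraries and from 9.47 to 74.7 in the other 6. IL24, a cytokine gene, was at 1677, 1530 and 1603 against 100 to 488. MAP2, a microtubule-binding protein gene, was at 282, 262 and 305 against 22.1 to 89.3. On the other end SGPP2, a lipid phosphatase gene, was at 10.4, 6.17 and 5.95 against 46.0 to 100, and the cell cycle phosphatase gene CDC25A at 179, 174 and 154 against 341 to 764.

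The libraries labelled control 3 and SKF-96365 1 each stood closer to the other group, by differences of mean r of which the smaller was 0.007. An exchange of labels between these libraries predicts such a difference above 0, and the size is small for SKF-96365 1. These correlations raised the question themselves, so they cannot decide it. Among all partitions the one with these labels exchanged ranked 3 by pseudo-F (3.07), after 3.51 and 3.24. The 5 highest all kept control 3 with SKF-96365 2 and SKF-96365 3, and differed in where the remaining libraries stood. The highest placed SKF-96365 1 with control 1 and 2-APB 3. The exchange stays open. Library depth is argued against by the totals, 15999490 reads in control 3, 16053348 in control 1 and 16495997 in SKF-96365 2, and after thinning to 1 total the r of control 3 to SKF-96365 2 still exceeded that to control 1 by 0.0269. Reads of other origin in control 3 stay open, as leaving out the genes high in it alone removed 12 of 17492 tested genes and the difference of mean r was 0.028 with and without them. Batch, culture or unequal response could give the same pattern and have no label to test.

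Hepatocyte transcripts were near 0 in all libraries. Too few reads is argued against by an upper 95% limit for ALB of at most 1.25 CPM in the 8 libraries with recovered reads, without SKF-96365 3. Loss of the genes from the annotation is argued against by 25 of 26 secretory genes with reads in some library. Cells without the hepatocyte programme predict that few liver transcription factors are expressed. Of 18 such factors 6 had a mean of at least 50, and HNF4A had a mean of 1.21, so this explanation remains. Which line the cells are was not tested, and the groups of the design give no biological explanation to test.

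Of 98 genes detected in control 3 alone, 49 were on a list of 265 cancer panel genes. Genes seen before the list was written were excluded, and this exclusion was widened following a first run. Of genes silent elsewhere (under 20), 24 of 36 list genes were high in control 3, against 23 of 7169 other genes (odds ratio 601, Fisher's exact p = 3.27e-47). Reads from a cancer gene panel library could give this pattern. Genomic DNA without selection of genes is argued against, as 0.321% of other silent protein-coding genes were high. DNA enriched for panel genes was not tested. Of 33 markers of other cell types outside the cancer gene list and under 5 elsewhere, 0 reached 20 in control 3. Markers on that list were left out, and genes on it such as KDR (47.0) and CSF1R (151) were high in control 3. Cells of another type are therefore argued against only for markers outside the list.

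Splits of the 6 libraries of each comparison were too few for a share under 0.05. As the labelled splits called 0 genes, every split gave as many, 10 of 10 for each comparison, which decides nothing. The highest other counts were 6121 for SKF-96365 against control, 1 for 2-APB against control and 0 for 2-APB against SKF-96365. The 6121 came from control 1, control 2 and SKF-96365 1 against control 3, SKF-96365 2 and SKF-96365 3, which points to a structure of the samples. As many called lists came from 4 of 10 splits (labelled 13, highest other 17), 9 of 10 (6, 13) and 4 of 10 (13, 16) in the same order. For the F test over 3 groups the labelled partition called 0 genes, so the 100 of 100 drawn partitions with as many were fixed beforehand. Of these, 15 called at least 1 gene, and the highest called 5539.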
